A study of Mus musculus with 6 samples.

How the data were processed

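Total RNA was taken from 6 subcutaneous KPC1199 tumours, 3 from lactating mice and 3 from control mice, and per the labels' protocols it was labelled with biotin as cRNA for 3' Affymetrix arrays. The deposited table holds 1 intensity for each of 45101 probe sets on each array, made with MAS5 per the submitters' processing notes. The MAS5 version is not given in the sources used here. The deposited intensity values are linear and positive, and the mean of each array after trimming 2% at each end was 500.0 on all 6 arrays, so the arrays had already been scaled to a common level. Scanner files and detection calls were not used here.

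The log2 ratio of 3' to 5' probe sets ranged from -0.427 to -0.403 for Gapdh and from 0.291 to 0.384 for Actb, with overlapping ranges in the groups. No pair of arrays had identical values at over 50% of probe sets. Gene names came from the platform annotation and were compared with a reference gene table through Entrez identifiers, which changed 0 symbols. 34958 probe sets had 1 gene symbol, 932 had several and 9211 had none. Of those with 1 symbol, 34754 matched the reference gene table by identifier and 204 kept the array's own name. Probe sets with several names or none were left out of the gene level. They were tested separately: of 2513 that passed the filter, 0 had an adjusted p under 0.05 in limma, and 50 had an unadjusted p under 0.05. No coordinates are given, since no genome build is given in the sources used here.

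Values were taken as log2 of the deposited signal plus 16, with no further normalization between arrays. A fold change is therefore on the log2(signal + 16) scale and understates the change of dim genes. Each of 18194 genes was represented by its probe set of highest mean. Genes were kept where at least 3 of the 6 arrays lay at or above their array's median, which left 11623 genes. Lactation was compared with control in limma 3.58.1 under R 4.3.3 (lmFit, eBayes with an intensity trend), with group as the only term and Benjamini-Hochberg adjustment at 0.05. The prior degrees of freedom were 3.07 beside 4 residual ones, and the median standard error of a log2 difference was 0.137. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

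The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. 46 gene lists covered pathways and cell types, and 43 had at least 5 tested members; the B cell, acinar pancreas and red blood cell lists had fewer and were not tested. Of 713 list entries, 71 had no named single-gene probe set here and were not analysed here. Lists were tested with camera in limma at a preset correlation of 0.01, with an estimated correlation and fry beside it. Whether camera used the intensity trend was not written into the design; the trend was used to match the gene fit, after a run without it had been seen, and 14 lists passed without it. A list's score is the mean log2 value of its members on an array, compared with an exact two-sided permutation test, and its standard error is that of the difference between 3 and 3 scores.

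Genes were named by a rule with 3 parts. In each direction up to 12 genes past the adjusted threshold were to be named, filled from genes with an absolute log2 difference of at least 1 and groups that did not overlap; none passed, and 8 higher and 6 lower genes met the filling rule. Of each list, up to 3 members with the largest difference were named where none passed. A set of genes of hormone and tumour biology was named whatever its values, and those of it with no named probe set here were not analysed here. Cpa3, Oasl2, Hdc, the immunoglobulin genes as a group and the single caseins Csn1s1 and Csn3 were chosen after their values were seen. Casein and whey genes as a set, Y-linked genes and Xist fall outside the rule and were taken for tests set before their values were seen.

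The fits were tested on simulated data made from the arrays' own means and spreads, with 200 of the 11623 genes changed in each of 5 tables. Noise was drawn independently for each gene, so the simulated lists lacked the correlation between genes of the real ones. At an adjusted p under 0.05 the gene fit gave 6.2 false calls per table on average. A list of 10 genes shifted by -0.8 was called in 5 of 5 tables by camera, and in 4 of 5 with an estimated correlation. Alternatives were quantile normalization, centring each array on its median, added constants of 1 and 64, no filter and a filter at the 70th percentile, other rules for probe sets of a gene, a fit with no trend, robust eBayes, array weights, replicate number as a block, and leaving out each array in turn.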

Results

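Gene expression was measured in 6 subcutaneous tumours grown from KPC1199 cells, a mouse pancreatic ductal adenocarcinoma line. 3 tumours came from lactating mice and 3 from control mice, and each tumour was hybridised to its own Affymetrix array. Cells were injected under the skin of the back, in the lactation group when a mouse was pregnant or had begun to nurse. Tumours were collected 20 days later from mice of matched age. The labels call the tumours biological replicates and do not say which lactation mice were pregnant and which were nursing at injection. Growth during pregnancy is therefore not set apart from growth during nursing. The 6 arrays were close to each other in level, with median signals from 99.3 to 111.0, and their number limits the precision. A first principal component holding 36.8% of the variance and a second holding 25.2% did not separate the groups.

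The comparison asks how a tumour's transcripts differ when it grows in a lactating host. No single gene passed the test over all genes. Among the 43 tested gene lists, the mast cell list stood furthest apart. All 9 members above the level filter had lower means in tumours of lactating mice, by 1.76-fold on average. The tenth, Hdc, was higher by 0.75 on the log2 scale. Interferon response genes and ductal epithelial genes were higher on average by 0.25 to 0.34 on the log2 scale, and macrophage genes were lower by 0.23, with more overlap between the groups. These lists passed at a preset correlation between genes, and none of them passed with an estimated one, at adjusted p values of 0.392 for mast cells and 0.724 for the others. Lists of prolactin and STAT5 signalling and of proliferation did not pass the test of lists, nor did the 6 milk genes and 7 oestrogen and progesterone response genes that could be tested, which leave out the caseins. The prolactin list was tested without Prlr, the prolactin receptor gene.

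Of 11623 genes tested with limma, 0 were higher and 0 were lower at a Benjamini-Hochberg adjusted p under 0.05. At an unadjusted p under 0.05 there were 264 genes, 175 higher and 89 lower in lactation, where chance alone would give 581. With each array centred on its median the split of such genes was 109 higher and 125 lower. Lactation and control values did not overlap for 431 genes higher and 371 genes lower, together 6.9% of the genes, where chance gives 10%. On simulated data of this size and spread, with noise drawn independently for each gene, the same fit recovered 78% of 2-fold changes and 97.2% of 4-fold changes. In the real arrays genes vary together, so these shares do not tell how many such changes were missed.

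Values are given below as the mean MAS5 signal ± SD over 3 arrays per group. Mcpt2, a chymase-type protease of mucosal mast cells, had a signal of 708 ± 67.7 in lactation and 2442 ± 833 in controls. This is a log2 difference of -1.71 with a standard error of 0.25, and limma's adjusted p was 1. Mcpt1, a second mucosal mast cell protease, measured 298 ± 101 against 1462 ± 800, a difference of -2.09. Chil3, a chitinase-like protein of alternatively activated macrophages, measured 110 ± 25.0 against 598 ± 675, and the log2 difference of -1.72 was -0.84 without control replicate 2, which had a signal of 1376.

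On the higher side, 8 genes had a log2 difference of at least 1 and groups that did not overlap, and none of them passed the adjusted test. Ighg3, an immunoglobulin heavy chain constant gene, had the largest difference of these, 2.36 with a standard error of 0.69, which was 1.51 without lactation replicate 2. Its other probe sets, all below the level filter, had differences of -0.294, -0.232 and 0.025. Prom1, a membrane glycoprotein of epithelial progenitor cells, measured 6644 ± 1018 in lactation and 3271 ± 1742 in controls. Muc4, a membrane mucin, measured 868 ± 109 against 455 ± 233, Hnf4a, a transcription factor of gut and liver epithelium, 502 ± 148 against 259 ± 132, and Krt5, a basal keratin, 505 ± 288 against 219 ± 64.2. Without control replicate 3 the log2 difference of Muc4 was 0.61 in place of 1.03 and that of Hnf4a 0.54 in place of 1.02, and without lactation replicate 3 that of Krt5 was 0.64 in place of 1.06. With the mean of its probe sets the difference of Muc4 was 0.59. The log2 difference was 1.04 for Hcar2, a receptor for hydroxycarboxylic acids, 1.06 for Cracdl and 1.82 for Oit1, which was 1.185 with an added constant of 64.

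**Figure D1:**
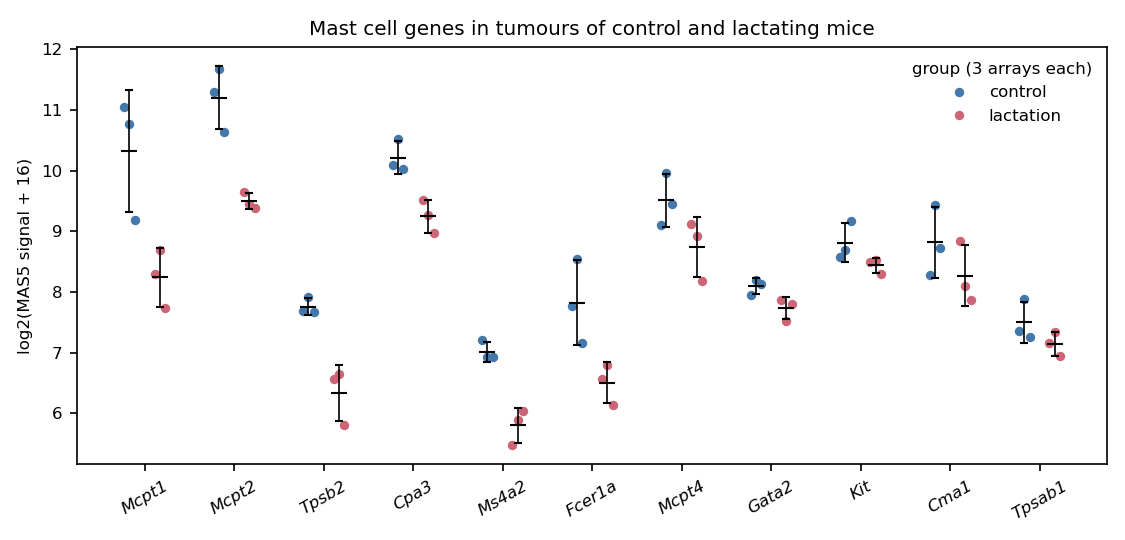
Level of Mcpt1, Mcpt2 and the 9 tested genes of the mast cell list on each array, as log2 of MAS5 signal plus 16. Points are arrays (3 control, 3 lactation), short lines are group means and bars are SDs. The 9 list genes have a lower mean in lactation. Mcpt1 and Mcpt2 are not in the list. They were named for a large difference and groups that do not overlap, so their lower values are no added support. Hdc, a member below the level filter, is not shown.

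Of 43 gene lists tested with camera at a preset correlation, 17 passed an adjusted p under 0.05, 9 higher and 8 lower in lactation. The split was 12 higher and 5 lower with arrays centred on their medians, and 9 and 5 after quantile normalization. With a correlation estimated for each list 0 of the 43 passed, with 1 at an unadjusted p under 0.05, and fry gave the same counts of 0 and 1. Without lactation replicate 2 the count of lists was 7.

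The mast cell list had the lowest p, with a mean log2 difference of -0.81 (standard error 0.19) and an adjusted p of 1.42e-12. The adjusted p was 0.392 with an estimated correlation. List scores, the mean log2 level of the 9 members, were 7.73, 7.67 and 7.34 in lactation and 8.22, 8.68 and 8.28 in controls. Their exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 allow. Scores did not overlap between the groups in 3 of the 43 lists, where chance gives 10%. Of the 9 mast cell members, 6 had groups that did not overlap, where chance gives 10% of genes. None of the 9 passed over all genes. In an adjustment over the list alone, which leaves out that this list was the most extreme of 43, 4 passed. These were Tpsb2, a tryptase (67.5 ± 24.2 against 201 ± 22.1), Ms4a2 and Fcer1a, chains of the high-affinity IgE receptor, and Cpa3, mast cell carboxypeptidase (600.5 ± 115 against 1186 ± 233). Ms4a2 measured 40.6 ± 10.9 against 114 ± 15.5 and Fcer1a 76.4 ± 20.6 against 229 ± 118. The lactation means of Tpsb2, Ms4a2 and Fcer1a lay under the array medians, where the added constant of 16 makes the fold changes understated, and all 3 passed the level filter through the control arrays alone. The tenth member, Hdc, the histamine-forming enzyme, lay below the filter and went the other way (150 ± 83.6 against 74.8 ± 9.45, a log2 difference of 0.75). With no filter the mean over all 10 members was -0.66 (standard error 0.17, adjusted p = 1.12e-08). The difference of Ms4a2 was -1.21, and -0.77 with an added constant of 64. Whether probe sets of related mast cell proteases share signal was not tested.

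Genes induced by interferons were higher in lactation by the list test. All 17 tested genes of the interferon gamma list had a positive difference, with a mean of 0.34 (standard error 0.26) and a camera adjusted p of 1.16e-08, and the adjusted p was 0.724 with an estimated correlation. 0 of the 17 passed over all genes and 0 when adjusted over the list alone. Igtp, an interferon-inducible GTPase, measured 10500 ± 3017 in lactation and 7497 ± 390 in controls, Tap1, a peptide transporter of antigen presentation, 1813 ± 492 against 1331 ± 216, and Ido1, a tryptophan-degrading enzyme, 411 ± 230 against 250 ± 163. Their log2 differences were 0.44, 0.42 and 0.65; without lactation replicate 2 they were 0.285, 0.223 and 0.377, without lactation replicate 1 those of Igtp and Ido1 were 0.705 and 1.247, and without control replicate 1 or 2 that of Ido1 was 0.28 or 1.12. In the type I interferon list 15 of 16 genes were positive, with a mean of 0.25 (standard error 0.20), an adjusted p of 5.29e-07 and an adjusted p of 0.724 with an estimated correlation. None of its genes passed over all genes and 3 passed when adjusted over the list alone, Oasl2, Oasl1 and Oas2, members of the oligoadenylate synthetase family, with log2 differences of 0.43, 0.44 and 0.57. Lactation replicate 2 had the highest score in both lists. Without it the type I mean was 0.09 with an adjusted p of 0.105 and the interferon gamma mean was 0.17 with an adjusted p of 0.0148, and without lactation replicate 1 these means were 0.40 and 0.55.

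Inflammatory cytokine genes of the NF-kB list had a mean difference of 0.25 (standard error 0.11) and an adjusted p of 0.000337, and the adjusted p was 0.724 with an estimated correlation. Of 17 genes 14 were positive, among them the neutrophil chemokine Cxcl5 with 0.82, Tnf with 0.96 and Cxcl2 with 0.59. The difference of Tnf was 0.28 without control replicate 2, which had a signal of 17.3 where the other controls had 105 and 142, and 0.61 with an added constant of 64, and that of Cxcl2 was 0.97 without control replicate 3. None passed over all genes or when adjusted over the list alone, and without lactation replicate 2 the list's mean was 0.15 with an adjusted p of 0.128. Antigen presentation genes had a mean of 0.13 (adjusted p = 0.00985; adjusted p = 0.805 with an estimated correlation), and their call ended without lactation replicate 2 or control replicate 1 or 3, at means of 0.01, 0.09 and 0.09 and adjusted p values of 0.941, 0.12 and 0.16. It also ended with array weights, at an adjusted p of 0.135 and the same mean, and the mean was 0.08 with centred arrays and 0.21 without lactation replicate 1. Plasma cell genes had a mean of 0.42 (adjusted p = 0.0267; adjusted p = 0.724 with an estimated correlation), led by the immunoglobulin chain Ighm with 1.29, which was 0.63 with the mean of its probe sets, and the joining chain Jchain with 0.72, which was 0.32 without control replicate 1 and 1.23 without control replicate 3. Without lactation replicate 1 or 2 or control replicate 1 the plasma cell list's adjusted p was 0.0619, 0.137 or 0.132, with means of 0.52, 0.32 and 0.27. With no filter the list had 9 tested members in place of 6, a mean of 0.25 and an adjusted p of 0.161.

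Ductal epithelial genes, which mark the tumour cells, had a mean difference of 0.31 (standard error 0.29). Their scores fell into 2 sets that cross the groups: lactation replicates 1 and 3 and control replicate 1 had 12.03, 12.17 and 11.96, and lactation replicate 2 and control replicates 2 and 3 had 11.47, 11.41 and 11.36. All 18 genes had a positive difference, 0 passed over all genes and 0 when adjusted over the list alone. The camera adjusted p was 6.19e-05, and the adjusted p was 0.724 with an estimated correlation. The membrane protein Tspan8 measured 4117 ± 1928 in lactation and 2554 ± 873 in controls, Muc1, a membrane mucin, 2731 ± 926 against 1841 ± 875, and the duct keratin Krt19 9661 ± 2189 against 7838 ± 1543. Without lactation replicate 3 the list's mean was 0.17 with an adjusted p of 0.063, and it was 0.52 without lactation replicate 2, 0.50 without control replicate 1 and 0.20 without control replicate 3. The log2 differences of Tspan8, Muc1 and Krt19 were 0.64, 0.60 and 0.29. When an array was left out they ranged from 0.295 (without lactation replicate 3) to 0.985 (without lactation replicate 2), from 0.34 (without control replicate 3) to 0.96 (without control replicate 1) and from 0.18 (without lactation replicate 3) to 0.495 (without lactation replicate 2).

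Macrophage and monocyte genes were lower, with a mean of -0.23 (standard error 0.18), 14 of 15 genes negative and a camera adjusted p of 2.25e-05; the adjusted p was 0.724 with an estimated correlation. None passed over all genes or when adjusted over the list alone. The integrin Itgam measured 204 ± 16.8 against 336 ± 97.2 and Cd68, a lysosomal protein of macrophages, 1482 ± 362 against 1865 ± 261, while Cd14, the co-receptor for lipopolysaccharide, measured 4949 ± 1237 against 3685 ± 796. Without lactation replicate 3 the list's mean was -0.07 with an adjusted p of 0.063 and the log2 difference of Cd68 was -0.13 in place of -0.35. Without control replicate 2 the mean was -0.15, and without lactation replicate 2 the difference of Cd14 was 0.64 in place of 0.41. Lists of stroma and of the epithelial-mesenchymal transition were lower by less. Mean differences were -0.11 for fibroblast and matrix genes, -0.13 for endothelial genes, -0.16 for TGF-beta response genes and -0.08 for genes of the epithelial-mesenchymal transition. Their adjusted p values were 0.033, 0.0285, 0.0274 and 0.0347, and with an estimated correlation the adjusted p values were 0.815, 0.805, 0.724 and 0.805. Without control replicate 3 the fibroblast, endothelial and transition lists had positive means of 0.09, 0.02 and 0.12, the fibroblast list with an adjusted p of 0.0133 in that direction, and the TGF-beta mean was -0.06 with an adjusted p of 0.605. Without control replicate 1 the fibroblast, endothelial and transition means were -0.27, -0.28 and -0.22, and without control replicate 2 the TGF-beta mean was -0.24. The endothelial call also ended without lactation replicate 1, 2 or 3 (adjusted p 0.0685, 0.069 and 0.116), where the mean was -0.15, -0.15 and -0.09. The fibroblast call ended without lactation replicate 1 or 2 (0.335 and 0.0611), with means of -0.07 and -0.14, and the transition call without lactation replicate 1 or 3 (0.276 and 0.063), with means of -0.004 and -0.09. The TGF-beta call ended without lactation replicate 2 or 3 or control replicate 1 (0.0611, 0.194 and 0.0724), with means of -0.17, -0.09 and -0.18. Quantile normalization ended the fibroblast and transition calls (0.117 and 0.0785), a fit with no trend did so too (0.0585 and 0.0587), and a filter at the 70th percentile ended the endothelial and transition calls (0.0837 and 0.0765). Array weights ended the fibroblast, TGF-beta and transition calls (0.231, 0.0964 and 0.126). The transition call also ended with no filter (0.0528) and with the mean of a gene's probe sets (0.09), and the means in these fits lay from -0.16 to -0.06. With arrays centred on their medians the means of the fibroblast, endothelial, TGF-beta and transition lists were larger, at -0.16, -0.18, -0.20 and -0.13, and their adjusted p values were 0.0555, 0.0746, 0.0555 and 0.0585.

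Among metabolic and stress lists, glycolysis genes had 13 of 13 positive differences with a mean of 0.10 (adjusted p = 0.00284; adjusted p = 0.724 with an estimated correlation). The liver-type phosphofructokinase Pfkl had the largest difference among the enzymes at 0.34, and without lactation replicate 3 the list's mean was 0.07 with an adjusted p of 0.063. Cholesterol synthesis genes had a mean of 0.13 (adjusted p = 0.000868; adjusted p = 0.724 with an estimated correlation), and a mean of 0.06 with an adjusted p of 0.188 without lactation replicate 2. Immediate early genes had a mean of 0.11 (adjusted p = 0.0267; adjusted p = 0.805 with an estimated correlation), and an adjusted p of 0.583 without lactation replicate 3. Oxidative phosphorylation genes had a mean of -0.05 (adjusted p = 0.0272; adjusted p = 0.805 with an estimated correlation), and an adjusted p of 0.466 without lactation replicate 2. Genes of the heat shock and unfolded protein response had a mean of -0.14 (adjusted p = 0.0137; adjusted p = 0.724 with an estimated correlation), and an adjusted p of 0.174 without control replicate 2. The calls of the immediate early, oxidative phosphorylation and heat shock lists each ended without lactation replicate 2 or 3 or control replicate 1 or 2, at adjusted p values from 0.0518 to 0.583. In these fits the means ranged from 0.01 to 0.12 for the immediate early list, from -0.06 to -0.03 for oxidative phosphorylation and from -0.14 to -0.05 for heat shock. Without lactation replicate 1 the immediate early and oxidative phosphorylation means were 0.21 and -0.10, and without control replicate 3 the heat shock mean was -0.245. The oxidative phosphorylation call also ended after quantile normalization (0.0785), with no trend (0.0656) and, as did that of heat shock, with the mean of a gene's probe sets (0.168 and 0.0643); the means there were -0.04, -0.05, -0.03 and -0.12. With arrays centred on their medians the means were 0.06 for glycolysis, 0.08 for cholesterol synthesis, 0.06 for immediate early genes and -0.10 for oxidative phosphorylation, all past the threshold. No gene of these 5 lists passed over all genes or when adjusted over the list alone.

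**Figure D2:**
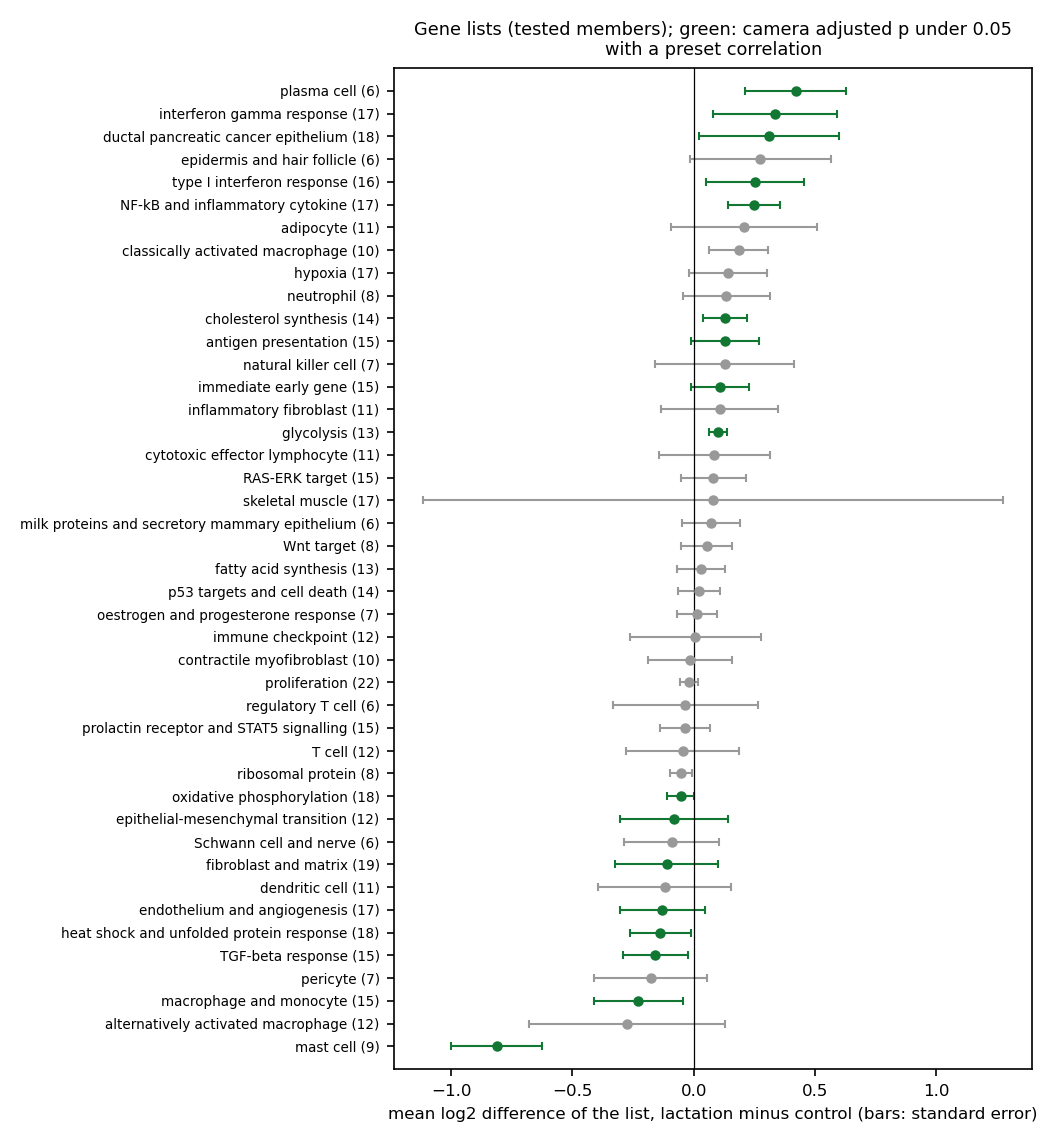
Mean log2 difference, lactation minus control, of each of the 43 tested gene lists, with the number of tested members in brackets. Bars are standard errors of the difference between 3 and 3 list scores; green marks the 17 lists with a camera adjusted p under 0.05 at the preset correlation, of which the mast cell list lies furthest from 0 at -0.81.

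The lists closest to the hormonal state of the host did not pass. Prolactin and STAT5 signalling genes, with 15 tested members of 17, had a mean difference of -0.04 (standard error 0.11, camera adjusted p = 0.934). Prlr, the prolactin receptor gene, had no named single-gene probe set and Elf5 lay below the filter. The oestrogen and progesterone response list, with 7 tested members of 16, had a mean of 0.01 (standard error 0.08, adjusted p = 0.871). Esr1, the oestrogen receptor, measured 530 ± 107 in lactation and 486 ± 69.7 in controls, and Pgr, the progesterone receptor, lay below the level filter with its brightest probe set at 37.1 ± 2.69 against 42.8 ± 5.83. The milk and secretory mammary list had 6 tested members of 22, with a mean of 0.07 (adjusted p = 0.871), and the beta-casein gene Csn2 was below the filter with a signal of 333 in lactation replicate 2 and at most 27 in controls. Proliferation genes had a mean of -0.02 over 22 genes (standard error 0.04, adjusted p = 0.563), and Mki67, a marker of cycling cells, measured 3632 ± 369 against 3502 ± 344. When an array was left out none of these 4 lists passed. Their means ranged from -0.109 (without lactation replicate 2) to 0.019 (without lactation replicate 3) for prolactin and STAT5 signalling, and from -0.052 (without control replicate 1) to 0.062 (without control replicate 3) for the oestrogen and progesterone response. For milk genes they ranged from -0.029 (without control replicate 2) to 0.177 (without control replicate 1), and for proliferation from -0.05 (without control replicate 1) to 0.001 (without control replicate 2).

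**Figure D3:**
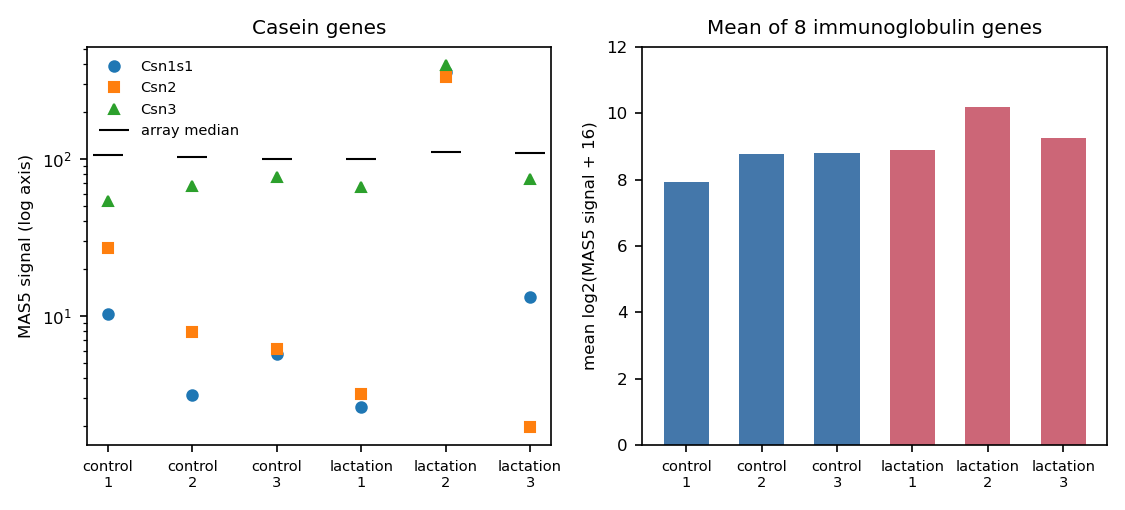
Left, MAS5 signal of 3 casein genes on each array (log axis) with each array's median as a black line; the caseins lie above the median in lactation replicate 2 alone, at 333 to 396. Right, mean log2 of signal plus 16 of 8 immunoglobulin genes on each array, from 7.92 to 8.81 in controls and from 8.9 to 10.19 in lactation.

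Lymphocyte lists did not pass either. Mean differences were -0.05 for T cells (standard error 0.23, camera adjusted p = 0.602), 0.09 for cytotoxic effector genes (adjusted p = 0.563), 0.13 for natural killer cells (adjusted p = 0.706), -0.03 for regulatory T cells (adjusted p = 0.872) and 0.01 for immune checkpoint genes (adjusted p = 0.923). These means depended on single arrays. Without control replicate 2 they were 0.164, 0.278, 0.328, 0.229 and 0.221, and the last 4 lists passed, at adjusted p values of 0.007, 0.0489, 0.0365 and 0.0272. The lowest means were -0.151, -0.068 and -0.146 for T cells, cytotoxic and natural killer genes without control replicate 3, and -0.253 and -0.153 for regulatory T cells and checkpoint genes without control replicate 1. Markers of tissue around a tumour did not pass, with means of 0.27 for epidermis and hair follicle over 6 tested members, 0.21 for adipocytes and 0.08 for skeletal muscle. With no filter the epidermis list had 17 members and a mean of -0.07, and over the 6 members the mean was 0.02 without lactation replicate 3 and 0.454 without lactation replicate 1. The adipocyte list passed with arrays centred on their medians (mean 0.16, adjusted p = 0.0225), with the mean of a gene's probe sets (0.26, 0.0248) with the replicate block (0.21, 0.0323), without lactation replicate 3 (0.369, 0.00831) and without control replicate 2 (0.449, 0.00027), and its adjusted p was 0.724 with an estimated correlation. Its mean was 0.017 with a filter at the 70th percentile, 0.055 without lactation replicate 2, 0.086 without control replicate 1 and 0.09 without control replicate 3. The muscle mean was -0.65 (adjusted p = 0.0165) without lactation replicate 1, -0.73 (adjusted p = 0.000387) without control replicate 3, 0.68 (adjusted p = 0.00831) without lactation replicate 3 and 0.84 (adjusted p = 0.00027) without control replicate 2, and 0.209 and 0.128 without lactation replicate 2 and control replicate 1, against 0.08 (adjusted p = 0.871; adjusted p = 0.965 with an estimated correlation) over all arrays. The muscle genes varied widely within both groups, from a score of 9.84 to 12.49 in lactation and from 9.34 to 12.48 in controls.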

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

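The search for signals below the level filter and the single-array test of this part were chosen after values had been seen, while the test on casein and whey genes was set before their values were seen. Probe sets of listed genes that failed the level filter were searched for a signal above the array median and at least 4 times the highest control in a lactation array. Of 296 probe sets 3 met this, all of them casein genes of milk and all in lactation replicate 2. Csn1s1 had a signal of 359 there against at most 10.3 in controls, Csn2 333 against at most 27, and Csn3 396 against at most 76.3, where the median of that array was 111. The mirror search in control arrays found 0.

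Immunoglobulin genes were higher in lactation by 0.95 on the log2 scale (standard error 0.48) as the mean of 8 genes, 7 of them positive. The exact permutation p was 0.1, the smallest possible. The group was chosen after values had been seen and holds Ighg3 (2.36) and Ighm (1.29), so its mean and p are no separate evidence. Igha had a difference of -0.07, with its highest log2 value, 13.29, in control replicate 3. Without lactation replicate 2, 60.9% of the difference was left, with scores of 8.9 and 9.26 in lactation against 7.92, 8.77 and 8.81 in controls. The group and this test were chosen after values had been seen. Whether lactation replicate 2 alone carries the difference is therefore not decided. Lactating mammary gland in the tumour samples remains a possible explanation: 7 casein and whey genes were higher by 0.53 on average (standard error 0.58), between the bounds set for and against it, with 4 of the 7 below the median on all lactation arrays. Its only sign was in lactation replicate 2, with a casein and whey score of 6.86. Lactation replicates 1 and 3 had 5.04 and 5.27, within the control range of 5.04 to 5.3. Without lactation replicate 2 the casein and whey difference was -0.04 and the immunoglobulin difference 0.58, and the lactating state of the host stays open and untested.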

How the results depend on the processing

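Counts of called genes were 0 higher and 0 lower in limma under all 18 alternatives, the lowest adjusted p being 0.0862 without control replicate 3. The count of gene lists was 17, ranged from 14 to 20 in alternatives that kept all arrays and camera's preset correlation, and from 7 (without lactation replicate 2) to 22 (without control replicate 2) when an array was left out. It was 0 with an estimated correlation and 0 with fry, which allow for the correlation between genes of a list. The replicate block gave 0 genes and 20 lists; the deviations of same-numbered arrays correlated at 0.143, -0.083 and 0.267, so the numbers were not taken to pair the arrays. The mast cell and interferon gamma lists passed in every camera alternative in which they could be tested at the preset correlation; a filter at the 70th percentile left too few mast cell genes. Robust eBayes does not apply to camera, and testing every probe set was not run for lists. Of the named genes' values, 8 reversed sign and 1123 did not. Atp5c1 was 0.053 with the mean of its probe sets. When an array was left out, Esr1 ranged from -0.038 to 0.226, Hspb1 from -0.99 to 0.052, Mki67 from -0.03 to 0.132, Pfkfb3 from -0.08 to 0.377, Snai2 from -0.61 to 0.172 and Tff2 from -0.068 to 1.544; the cause was not tested. Genes near the array median have little signal over background, which limits what could be called for them.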

Other observations

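All single-array tests, and those on soft tissue, tumour share and lymphocytes, were chosen after the results were seen. Skeletal muscle genes varied more between arrays than any other tested list, with scores of 12.49, 10.78 and 9.84 in lactation and 11.05, 12.48 and 9.34 in controls. The fast myosin gene Myh4 ranged from 1572 to 13490 in lactation and from 562 to 12560 in controls. Ductal epithelial scores were 12.03, 11.47 and 12.17 in lactation and 11.96, 11.41 and 11.36 in controls.

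Of 3 technical explanations set against the lower level of mast cell genes, the first was a dilution of all host cells alike. The mast cell list lay -0.69 (standard error 0.11) beyond the mean of 5 other host lists, which was -0.13, and -0.54 (standard error 0.11) with no filter. The mast cell list was picked as the furthest from 0 of the 43 lists, which favours such a gap. The comparison therefore does not decide on dilution. The second was a single array. At least 82.6% of the difference was left whichever array was removed, so none of these arrays alone held most of it. The pick of the list favours a large share left as well, and this test was chosen after the results were seen. It therefore describes these arrays and does not decide on a single array as the cause. Less skin and soft tissue around the tumours cannot be told apart from other explanations: epidermis, adipocyte and muscle lists differed by 0.19 on average, and by 0.07 with no filter, and the gaps of 0.59 (standard error 0.32) and 0.40 (standard error 0.34) to the bound of 50% of the mast cell difference were under 2 standard errors. This verdict turned on a bound changed after the result was seen: an earlier bound, 1 standard error with the filter, was exceeded and would have counted against soft tissue. Signal shared between related proteases was not tested, and fewer mast cells, or less of their transcripts per cell, in lactating mice stays open and untested.

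The higher type I interferon response fits a contribution of a single array, and the interferon gamma response does so narrowly. Without lactation replicate 2, the array with casein signal, 35.8% of the type I difference and 49.5% of the interferon gamma difference were left. The interferon gamma list still passed camera at the preset correlation then (adjusted p = 0.0148). Its scores in lactation replicates 1, 2 and 3 were 10.79, 11.57 and 11.32, and in controls 10.69, 11.09 and 10.9. Type I scores were 9.74, 10.36 and 10 in lactation and 9.69, 9.67 and 9.97 in controls. In both lists lactation replicate 1 lay within the control range. More T and natural killer cells cannot be told apart from the other explanations: their 3 lists were higher by 0.06, and the gap of -0.09 to the bound had a standard error of 0.24. A response of the lactating host stays open and untested.

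A hypothesis set before its values were seen was that Y-linked genes of a male tumour line could measure the tumour share. Their mean minus Xist differed by 0.2 (standard error 0.27), but 0 of the 3 Y-linked genes with a named probe set reached the array median in 3 arrays, so the test decides nothing.

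The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. For called genes the real counts were 0 and 0, the highest other split had 8 in a direction, and 10 of 10 splits gave as many in each direction. For genes at an unadjusted p under 0.05 the real count was 264 and the highest other 1256, with 9 splits as large. For gene lists the real count was 17 and the highest other 21, with 4 splits as large. The split with 1256 genes set lactation replicates 1 and 3 with control replicate 1. It had 0 called genes, and its list of lowest p was ductal epithelium. The split of lactation replicate 1 with control replicates 1 and 2 had 8 and 4 called genes. It had 1050 genes at an unadjusted p under 0.05, and its list of lowest p was skeletal muscle. Both splits were picked for their size among the 10, so they do not decide whether the samples have a structure apart from the groups. The lowest unadjusted camera p of a list was 3.31e-14 in the real split, for mast cells, and it was lower in 4 other splits, down to 2.93e-25 for the interferon gamma list. The mast cell list itself had a camera adjusted p of 1.42e-12 in the real split. Some other splits also called it, at adjusted p values of 0.0221, 0.018, 0.0321 and 0.00144. The rest did not, at 0.142, 0.587, 0.293, 0.677 and 0.278.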
